A study of Mus musculus with 32 samples.

How the data were processed

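RNA was measured in oocytes at the germinal vesicle stage (GV) and at metaphase II (MII) of B6, D2 and B6xD2 F1 female mice aged 8 to 12 weeks. Per the labels' protocols, GV oocytes were collected with the phosphodiesterase inhibitor IBMX, zonae were removed with acid Tyrode's solution, and each pool of 9 to 20 oocytes came from a single mother. RNA was extracted with a column kit and DNase treated, amplified by single primer isothermal amplification (SPIA), sheared, and made into libraries with 12 PCR cycles. Per the same protocols, the batches were sequenced on different HiSeq models, as single reads of 50 nt. Per the submitters' processing notes, reads were aligned with HISAT2 to GRCm38.p4, handled with SAMtools and counted with featureCounts of Subread 1.5.1, and DESeq2 1.16.1 was used afterwards. Strand and multi-mapping settings were not given in the sources used here. The deposited table holds the authors' read counts per gene, not normalised, with NCBI gene identifiers.

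The table had 37444 entries, of which 3 named no gene, 2 of them being fragments of coordinates, and these held at most 0.019% of a library. The other 37441 were kept. A RefSeq name was found for 36371 of them, and genes without one held 0.2123% of all counts. The reference used for names, transcript lengths and gene order was GRCm38. Every column was mapped to a sample by its group and number. Depth and the number of replicates set the precision. The SDs and SEs given include the spread between libraries, while floors cover counting error only, since reads had no molecular identifiers. In the ratios of pooled levels, MII counts under 3 over the stage were raised to a floor of 3 counts.

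Genes were filtered with filterByExpr on the 6 groups, and counts were scaled by TMM (trimmed mean of M values). A single model with the 6 groups and batch as terms was fitted to the 32 libraries with edgeR's robust quasi-likelihood functions. Two-sided tests were adjusted by Benjamini-Hochberg within each of 14 contrasts, with a threshold of 0.05. The SE of a log2 change was its size divided by the square root of the F value. Contrasts set MII against GV as a mean and in each strain, D2 against B6, F1 against each parent and against the mid-parent (mean of the parents' log2 levels) at each stage, and the stage change between strains. A gene was beyond both parents when it passed against each in the same direction.

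Of 22 gene lists, 21 were tested in 7 contrasts with limma's camera, with the correlation between genes estimated per list on log2 CPM with a prior count of 3. A preset correlation and fry were alternatives. The lists held cytosolic and mitochondrial ribosomal proteins, nuclear respiratory chain genes, proteasome, mRNA decay, translational control, antioxidant, granulosa and cumulus, stroma and blood, cohesin with spindle and checkpoint, DNA repair, glycolysis, maternal chromatin, meiotic kinases, oocyte-secreted and zona, subcortical maternal complex, pyruvate and citric acid cycle, cholesterol synthesis, heat shock with immediate early, interferon response, and strain label genes. Of 794 members as written, 13 had no entry in the table. These were the mitochondrially encoded respiratory chain genes, a list that was not analysed here.

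Groups, contrasts, lists, thresholds, most other settings tried and the rule for naming genes were chosen before the data were examined. The rule named genes past the threshold with a mean of at least 5 CPM and the same direction in both batches, taking the 5 largest folds in each direction. It added up to 4 called members per list with the lowest adjusted p, and the strain label genes in the parental contrasts. Predicted genes and pseudogenes were passed over, and all called genes were taken where there were under 5. Some genes that met the rule are not reported here.

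The other settings set down beforehand were other scalings (median of ratios, upper quartile), no filter or 1 CPM in at least 16 libraries, DESeq2 and limma-voom, a threshold of at least 2-fold, each batch alone, no batch term, a batch term of 3 levels (batch 1 and the 2 sets of batch 2 that differ in the date in the library name), the compared groups alone, a replicate block, and each library left out. Alternatives added after the data were seen were the granulosa marker level as a covariate, leaving out 3 GV libraries with low granulosa marker levels, and the arithmetic mean of the parents. The fit was tested on simulated data for D2 against B6 in MII with 200 changed genes among 19003, 50 at each fold. It recovered 10% at 1.5-fold, 44% at 2-fold, 52% at 4-fold and 66% at 8-fold, with 1 unchanged gene called. The arithmetic mid-parent was tested with limma-voom. For it, simulated MII data had 500 additive genes, of which 1 was called, against 321 on the log2 scale, while 84 of 100 genes raised 2-fold were recovered. Software was R 4.3.3, edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.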

Results

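The data were RNA-seq read counts per gene from mouse oocytes at 2 stages and in 3 kinds of female, the inbred strains B6 and D2 and their B6xD2 F1 hybrid. Germinal vesicle (GV) oocytes are arrested in prophase of the first meiotic division, and metaphase II (MII) oocytes are mature eggs arrested before fertilization. Each of the 32 libraries was made from a pool of 9 to 20 oocytes of a single mother. There were 6 groups, with 5 libraries of B6 GV, 6 of B6 MII, 5 of D2 GV, 5 of D2 MII, 6 of F1 GV and 5 of F1 MII. Each group held 3 libraries of batch 1 and 2 or 3 of batch 2, which was sequenced on another instrument. Total counts ran from 18.7 to 39.7 M reads per library, with a median of 28.1 M. Between 17673 and 25439 genes had at least 1 read in a library, and 19003 genes were tested. The first principal component of log2 CPM (counts-per-million) held 33.05% of the variance. Batch was a term in the main fit, and 8050 genes differed between the batches.

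The first comparison asked how the oocyte's transcripts differed between GV and MII, averaged over the 3 strains. Transcripts of 3 genes of the zona pellucida, the coat of the growing oocyte, fell. Zp3 was at 1250 ± 357 CPM in B6 GV oocytes (SD, n = 5) and 323 ± 107 in B6 MII oocytes (SD, n = 6). Zp2 fell by 1.77 ± 0.08 on the log2 scale (SE), and Zp1, named after its values were seen, fell by 0.45 ± 0.07. Khdc3, which encodes a member of the subcortical maternal complex, fell by 3.34 ± 0.13, and Cpeb1, a regulator of cytoplasmic polyadenylation, fell by 1.62 ± 0.06. Omt2b, an oocyte-expressed gene, rose from 618 ± 374 to 2760 ± 551 CPM in B6. Btg4, an adaptor of the deadenylase that removes maternal mRNA, rose from 711 ± 168 to 1190 ± 141 CPM. Nip7, a ribosome biogenesis factor, rose by 1.72 ± 0.13 on the log2 scale and Fubp3, an RNA-binding protein, by 1.59 ± 0.12. Each of the 16 MII libraries lay below every GV library for Zp3, Zp2 and Cpeb1 and above every GV library for Omt2b and Fubp3, and 15 of 16 did so for Khdc3 and Btg4. For Nip7, 10 of 16 lay above every GV library. In edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, adjusted p was 8.43e-21 for Zp3, 3.57e-20 for Khdc3, 6.06e-21 for Cpeb1, 4.92e-13 for Omt2b and 1.15e-10 for Btg4. Omt2b has a near-identical neighbour, Omt2a, with which it can share reads, so the split of counts between the pair is uncertain.

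**Figure D1:**
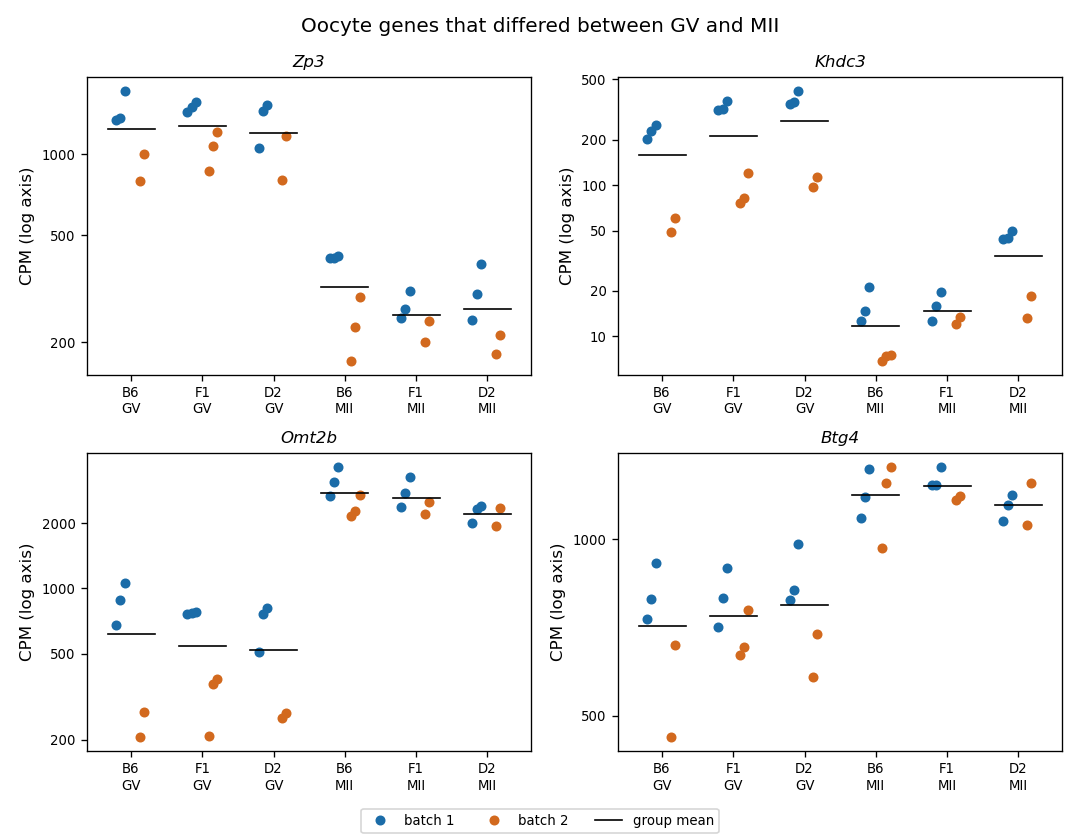
CPM (log axis) of Zp3, Khdc3, Omt2b and Btg4 in each library of the 6 groups, with batch 1 in blue, batch 2 in orange and black lines for group means. Zp3 and Khdc3 were lower and Omt2b and Btg4 higher in MII groups than in GV groups.

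In total 9862 genes differed between the stages by the same test, 4354 higher and 5508 lower in MII, and of these 155 were at least 2-fold higher and 3928 at least 2-fold lower. Genes called in each strain separately numbered 5065 in B6 (1957 higher, 3108 lower), 6244 in F1 (2826 higher, 3418 lower) and 5461 in D2 (2496 higher, 2965 lower), and 1163 genes were higher and 1688 lower in all 3. Calls in B6 and D2, which share no library, overlapped at 1270 higher and 1906 lower genes against 257 and 484.9 for independent lists, with 4 genes in opposite directions, and fold changes correlated at r = 0.713 across genes, which are not independent replicates. Within batch 1 alone 9028 genes passed (3540 higher, 5488 lower), and within batch 2 alone 4503 (1819 higher, 2684 lower). The granulosa marker level, described below with the other cell types, was lower in MII too, although 3 GV libraries lay within the MII range. With that level as a covariate 2497 genes passed, 1006 higher and 1491 lower. With a stricter filter on low counts (1 CPM in 16 libraries), 3670 genes were higher and 3332 lower, of which 1564 at least 2-fold lower. Per oocyte, total RNA was not measured, so every change is relative to the rest of the library.

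Most transcripts of cytosolic ribosomal proteins and of the respiratory chain fell. Of 78 cytosolic ribosomal protein genes, 77 fell (77 adjusted over the list alone), with a median log2 change of −2.51 and adjusted p = 0.00249 with an estimated correlation in the camera test. Rps13 fell from 94.1 ± 70.4 CPM in B6 GV oocytes (SD, n = 5) to 1.64 ± 1.36 in B6 MII oocytes (SD, n = 6), and Rps4x fell by 3.33 ± 0.10 on the log2 scale (SE). Of 78 nuclear genes of the respiratory chain, 74 fell and 1 rose (the same counts adjusted over the list alone), with a median of −1.62 and adjusted p = 7.01e-05 with an estimated correlation. Atp5e, a subunit of ATP synthase, fell from 60.7 ± 39.9 to 3.05 ± 1.87 CPM in B6, and Ndufb5, a subunit of complex I, fell by 2.96 on the log2 scale. Among 78 mitochondrial ribosomal protein genes, 46 fell and 4 rose (47 and 4 adjusted over the list alone, median −0.435, mean −0.74, adjusted p = 0.0195 with an estimated correlation), including Mrpl33, which fell by 3.45. Among 45 proteasome genes, 33 fell and 6 rose (34 and 6 adjusted over the list alone, median −0.57, adjusted p = 0.0195 with an estimated correlation), including the core subunit gene Psmb7, which fell from a pooled level of 115 to 22.8 CPM. The mean log2 CPM of the ribosomal list was 6.52 ± 0.22 in GV and 3.74 ± 0.36 in MII in batch 1 (SD, 9 libraries each) and 4.74 ± 0.21 and 2.46 ± 0.15 in batch 2 (SD, 7 libraries each), with every MII library below the lowest GV library of its batch. The granulosa marker level moved with these lists between stages. The mitochondrial ribosomal list did not pass in batch 1 alone, at adjusted p = 0.134 (5.79e-13 to 0.134 over its alternatives). The proteasome list did not pass in batch 2 alone, at adjusted p = 0.0886 (8.69e-14 to 0.0886 over its alternatives).

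**Figure D2:**
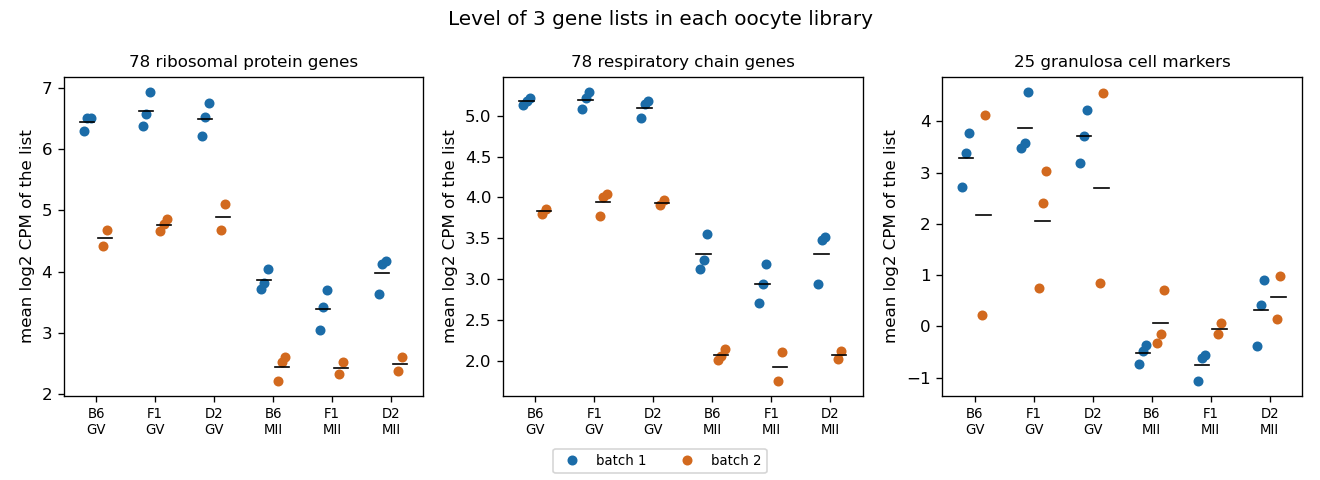
Mean log2 CPM over the genes of 3 lists (ribosomal proteins, respiratory chain, granulosa cell markers) in each library, by group, with batch 1 in blue, batch 2 in orange and black lines for the mean of each group and batch. MII libraries lay below GV libraries of the same batch for the ribosomal and respiratory chain lists, while 3 GV libraries of batch 2 had granulosa marker levels within the MII range.

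In the lists for mRNA decay and translational control more genes rose than fell, although the mean change of each list was near 0. More genes also rose than fell in lists that did not pass, such as maternal chromatin (16 and 7 of 27, median 0.335). The same held for cohesin, spindle and checkpoint genes (22 and 6 of 41, median 0.275). The estimated correlation was −0.006 for mRNA decay and for translational control, against 0.158 for maternal chromatin and 0.145 for the cohesin list. With the preset correlation each of these lists passed, so the estimate bears on which lists were called. Of 35 genes for mRNA decay, 19 rose and 6 fell (20 and 6 adjusted over the list alone), with a median of 0.26, a mean of −0.02 and an upward call by the list test at adjusted p = 0.00172 with an estimated correlation. The mean log2 CPM of that list was 6.33 ± 0.07 in GV and 6.29 ± 0.08 in MII in batch 1 (SD, 9 libraries each), and 6.26 ± 0.13 and 6.37 ± 0.08 in batch 2 (SD, 7 libraries each). Besides Btg4, the decapping gene Dcp1a rose by 0.70 ± 0.06 on the log2 scale (SE). Of 30 genes of translational control, 18 rose and 6 fell (18 and 6 adjusted over the list alone, median 0.25, mean 0.00, adjusted p = 0.0183 with an estimated correlation). Cpeb4 rose by 0.56, whereas Pabpc1, a poly(A)-binding protein, fell by 1.64 ± 0.17, a call that was lost with the granulosa level as a covariate. With that covariate 11 genes for mRNA decay rose and 2 fell, and 6 of translational control rose and 1 fell. The list of translational control did not pass within either batch alone, at adjusted p = 0.139 in batch 1 and 0.0984 in batch 2, nor with a stricter filter on low counts, at 0.133 (1.20e-09 to 0.139 over its alternatives). Of 39 antioxidant genes, 24 fell and 3 rose (the same adjusted over the list alone), at adjusted p = 0.0411 with an estimated correlation, among them the glutathione peroxidase Gpx4, which fell by 2.81 ± 0.31. The level of this list moved with the granulosa markers within GV libraries of batch 2. Its mean log2 CPM was 2.32, 2.40 and 2.59 in the 3 with a low granulosa marker level and 2.87 to 3.66 in the other 4, against 1.81 to 2.39 in MII libraries of that batch. The antioxidant list was at adjusted p = 0.222 in batch 2 alone and 0.0529 with median-of-ratios scaling (4.02e-11 to 0.222 over its alternatives).

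The other 14 lists did not pass with an estimated correlation. Among 41 cohesin, spindle and checkpoint genes, 22 rose and 6 fell (23 and 6 adjusted over the list alone, adjusted p = 0.318 with an estimated correlation), with the survivin gene Birc5 at −1.36 and the kinetochore gene Spc24 at −2.81 on the log2 scale. Among 38 genes of meiotic kinases and their regulators, 17 rose and 8 fell (18 and 8 adjusted over the list alone, adjusted p = 0.192), and Fbxo43, an inhibitor of the anaphase-promoting complex that holds MII arrest, rose by 0.63 ± 0.06 (SE). Among 54 DNA repair genes, 21 rose and 8 fell (21 and 10 adjusted over the list alone, adjusted p = 0.337). Among 27 maternal chromatin genes 16 rose and 7 fell (17 and 7 adjusted over the list alone, adjusted p = 0.318), with the maintenance methyltransferase Dnmt1 at −0.92 ± 0.08. Oocyte-secreted and zona genes split, with 12 rising and 10 falling of 24 (12 and 10 adjusted over the list alone, adjusted p = 0.806), as did the subcortical maternal complex list, with 8 rising and 6 falling of 18 (9 and 6 adjusted over the list alone, adjusted p = 0.952). Of 19 glycolysis genes 11 fell and 1 rose (11 and 1 adjusted over the list alone, adjusted p = 0.337). Of 26 genes of pyruvate and the citric acid cycle 10 fell and 6 rose (12 and 9 adjusted over the list alone, adjusted p = 0.633). Of 23 cholesterol synthesis genes 7 fell and 4 rose (7 and 4 adjusted over the list alone, adjusted p = 0.952). Of 26 heat shock and immediate early genes 10 fell and 4 rose (10 and 4 adjusted over the list alone, adjusted p = 0.467). Of 24 interferon response genes 13 fell and 4 rose (13 and 4 adjusted over the list alone, adjusted p = 0.421). Of the 8 measured genes kept to check strain labels 4 fell and 1 rose (5 and 1 adjusted over the list alone, adjusted p = 0.467). For the mRNA decay, DNA repair, oocyte-secreted and subcortical maternal complex lists the test pointed up with a positive median while the mean was negative, at −0.02, −0.06, −0.14 and −0.17. With a preset correlation of 0.01 in camera 14 of the 21 lists passed, and with an estimated correlation 7 did.

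Markers of the granulosa and cumulus cells that surround the oocyte were present in GV pools and far lower in MII pools. The pooled level of Inhba, which encodes an inhibin and activin subunit, was 319 CPM in GV and 2.75 in MII libraries. That of the steroidogenic gene Hsd3b1 was 329 and 5.57, that of Inha 62.0 and 0.229, and that of the luteinizing hormone receptor gene Lhcgr 64.4 and 0.287. Of 25 measured markers, 19 fell and 2 rose (20 and 2 adjusted over the list alone), with a median of −5.33, or −5.04 from pooled counts with MII counts under 3 raised to a floor of 3 counts over the stage, and adjusted p = 0.281 with an estimated correlation. Of these markers 8 were at 5 CPM or more in MII libraries, among them Esr2, with pooled levels of 59.7 CPM in GV and 59.3 in MII. Of 22 stroma and blood markers, 13 fell and 1 rose (the same adjusted over the list alone, median −2.84, or −3.18 at the floor, adjusted p = 0.318 with an estimated correlation), and the globin gene Hbb-bs had no read in MII libraries. Its reads in GV came mostly from a single library, D2 GV batch 1 replicate 3, at 199.8 CPM, and some GV libraries had none. The mean log2 CPM of the granulosa list was 2.85 ± 1.55 in B6 GV (SD, n = 5), 3.31 ± 1.47 in D2 GV (n = 5) and 2.97 ± 1.30 in F1 GV (n = 6), against −0.23 ± 0.49 (n = 6), 0.42 ± 0.56 (n = 5) and −0.47 ± 0.44 (n = 5) in the MII groups. In 3 GV libraries of batch 2 it lay within the MII range over all strains. It was at 0.23 in B6 GV replicate 1, 0.75 in F1 GV replicate 1 and 0.84 in D2 GV replicate 2 of that batch. The F1 library lay above every F1 MII library, the highest of which was at 0.068. Without those 3 libraries the granulosa list passed at adjusted p = 0.0498 (1.33e-07 to 0.599 over its alternatives). They were chosen for their low level of this same list, which favours a pass, so no conclusion is drawn from it. Of the 3928 genes at least 2-fold lower in MII, 907 were still so called with the granulosa level as a covariate, 1772 in batch 2 alone, 1431 with the stricter filter, where fewer genes are tested, and 3821 without those 3 libraries.

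The next comparison was between the parental strains at each stage. Pnpla3, which encodes a lipid droplet acyltransferase, was at 1.75 ± 0.979 CPM in B6 GV and 303 ± 35.2 in D2 GV oocytes (SD, n = 5 each), and at 1.13 ± 0.348 (n = 6) and 292 ± 36.6 (n = 5) in MII oocytes. Bfsp1, a filament protein of the lens, and Gsto2, a glutathione transferase, were higher in D2 by 8.92 ± 0.35 and 8.12 ± 0.40 on the log2 scale in GV (SE) and by 7.99 ± 0.32 and 7.68 ± 0.38 in MII. The vomeronasal receptor genes Vmn1r139, Vmn1r157 and Vmn1r112 were lower in D2, at −8.25, −8.12 and −7.96 in GV, but belong to a family of close copies whose reads can be shared. In MII, Pxdn, which encodes peroxidasin, was higher in D2 at 8.25 ± 0.36 and Sh3rf2 lower at −8.33 ± 0.35. Among well expressed genes of known function, the glycolytic enzyme gene Gpi1 was at 46.2 ± 15.1 CPM in B6 GV and 13.2 ± 3.54 in D2 GV. The kinetochore gene Ndc80 was at 114 ± 23.1 and 28.8 ± 4.87, and the mitochondrial ribosomal gene Mrps27 at 19.8 ± 4.13 and 75 ± 14.3 (SD, n = 5 each). All 5 D2 libraries lay beyond every B6 library for these 3 genes at both stages. Adjusted p in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment was 1.46e-24 in GV and 2.14e-26 in MII for Pnpla3, 2.78e-09 and 2.31e-12 for Gpi1, and 1.73e-11 and 7.09e-10 for Ndc80.

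**Figure D3:**
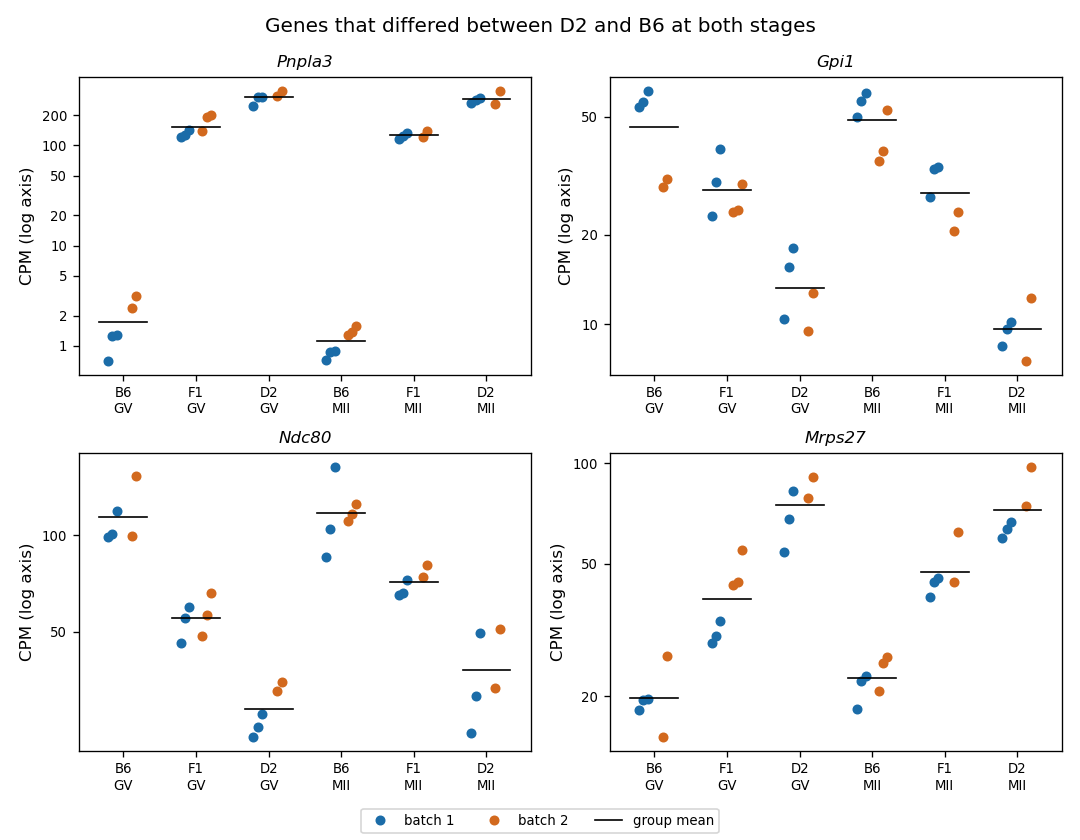
CPM (log axis) of Pnpla3, Gpi1, Ndc80 and Mrps27 in each library of the 6 groups, with batch 1 in blue, batch 2 in orange and black lines for group means. F1 group means lay between those of B6 and D2 for the 4 genes at both stages.

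In all, 3891 genes differed between D2 and B6 in GV oocytes (1740 higher and 2151 lower in D2, of which 849 and 1154 by at least 2-fold) and 5019 in MII oocytes (2552 higher and 2467 lower, of which 1306 and 1492 by at least 2-fold). The GV and MII lists, which share no library, had 1339 higher and 1493 lower genes in common against 233.7 and 279.2 for independent lists, with 3 in opposite directions and r = 0.648 across genes. Batch 1 alone gave 2449 genes in GV (1216 higher, 1233 lower) and 3439 in MII (1590 higher, 1849 lower), and batch 2 alone 1942 (967 higher, 975 lower) and 2160 (1059 higher, 1101 lower). Reads were aligned to a B6-derived genome, so sequence variants of D2 could lower D2 counts at single genes.

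No gene list passed between the strains with an estimated correlation, at adjusted p from 0.976 to 0.993 in GV and from 0.797 to 0.917 in MII, and neither did any with the preset correlation. At an unadjusted p under 0.05 the count was 0 at both stages, while the rotation test fry, which does not compare a list with other genes, called 2 lists in GV and 6 in MII. The test's direction and the signs of median and mean did not all match in 4 lists in GV and 6 in MII, among them mRNA decay in MII, with an upward test, a median of −0.03 and a mean of 0.21. Single members did differ. In MII, granulosa markers differed too, with 7 of 25 higher in D2 and 1 lower (8 and 1 adjusted over the list alone, median 1.08). Called markers included Cyp19a1, at pooled levels of 30.4 CPM in GV and 31.5 in MII, and Esr2, at 59.7 and 59.3. These did not follow the fall of the list between stages, so more granulosa-cell RNA in D2 MII pools cannot be read from these calls. In MII also, 12 of 35 mRNA decay genes were higher in D2 and 2 lower (12 and 3 adjusted over the list alone). The decapping activators Lsm1 and Ddx6 were higher by 1.45 ± 0.19 and 1.32 ± 0.16 on the log2 scale (SE). Of 18 subcortical maternal complex genes 6 were higher and the rest not called (6 adjusted over the list alone), with Khdc3 higher by 1.33 ± 0.21 and Nlrp2 by 0.73 ± 0.11. Of 54 DNA repair genes in GV 11 were lower and 3 higher (the same adjusted over the list alone), with Brca2 at −0.82 ± 0.11 and Fanci at −1.21 ± 0.20, while Lig4 was higher by 0.805 ± 0.13. The immediate early gene Egr1 was higher in D2 by 1.22 ± 0.10 in GV and 1.25 ± 0.10 in MII, and the sterol genes Sc5d and Msmo1 went opposite ways in MII, at −2.25 ± 0.26 and 1.74 ± 0.24. Of 24 interferon response genes in MII 7 were lower and 1 higher (8 and 1 adjusted over the list alone), with the RNA-activated kinase gene Eif2ak2 at −2.04 ± 0.595. The ribosomal list split in MII, with 9 higher and 7 lower of 78 (9 and 6 adjusted over the list alone), Rpl15 being higher by 2.14 ± 0.18 and Rpl37 at −2.23 ± 0.26, and 7 of 78 respiratory chain genes were called, 4 higher and 3 lower (3 and 1 adjusted over the list alone).

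Genes known to differ between these strains served to check the labels. Nnt, part of which is deleted in the C57BL/6J substrain, was at 0.156 ± 0.126 CPM in B6 MII (SD, n = 6) and 2.56 ± 2.52 in D2 MII oocytes (n = 5), higher by 4.05 ± 0.68 on the log2 scale (SE, adjusted p = 1.68e-05, edgeR quasi-likelihood with Benjamini-Hochberg adjustment), and did not pass in GV, at 1.35 ± 0.64 (adjusted p = 0.146). Gpnmb, which carries a stop codon in DBA/2J, was lower in D2 at −1.03 ± 0.26 in GV and −1.23 in MII, and Myo5a, the site of the dilute coat colour allele, was lower at −1.01 ± 0.10 and −0.71 ± 0.10. Wdfy1 was higher by 1.12 and 1.32, and Entpd4 lower at −1.35 and −1.23. Hc passed in GV, at −1.26, and not in MII, at −0.73 (adjusted p = 0.109). Glo1 did not pass, at 0.99 in GV (adjusted p = 0.0565) and 0.41 in MII (adjusted p = 0.427).

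The series asked how hybridization affects the oocyte, and F1 libraries were first set against each parent. In GV oocytes 1045 genes differed between F1 and B6 (538 higher, 507 lower) and 1149 between F1 and D2 (774 higher, 375 lower). In MII oocytes the counts were 1399 (886 higher, 513 lower) and 1542 (934 higher, 608 lower). Batch 1 alone gave 216, 474, 640 and 907 genes for these 4 comparisons and batch 2 alone 992, 325, 223 and 343. By the dates in the library names, whose meaning is not stated, all B6 libraries of batch 2 belonged to 1 of 2 sets and both F1 MII libraries to the other, while D2 libraries of each stage and F1 GV libraries were in both. With a term for these sets 776 genes differed between F1 and B6 in GV and 1139 in MII. The F1 level of Gpi1 was 28.3 ± 6.04 CPM in GV (SD, n = 6) and 27.7 ± 5.87 in MII (n = 5), between the parents, and that of Ndc80 was 55.3 ± 7.32 and 71.7 ± 6.32. Over the genes that differed between the parents, the position of the F1 was measured on the log2 scale. With 0 as the middle, 0.5 as the D2 level and −0.5 as the B6 level, the median position was −0.0022 in GV (interquartile range −0.1775 to 0.1727, 3891 genes) and −0.0217 in MII (−0.209 to 0.1651, 5019 genes). This median combines genes high in B6 with genes high in D2. Among genes at least 8-fold apart between the parents, the F1 lay a median of 1.04 above the middle on the log2 scale in GV (692 genes) and 0.75 in MII (981 genes), while against the arithmetic mean of the parents the medians were −0.24 and −0.40. Within batches the median position was −0.062 in batch 1 and 0.111 in batch 2 for GV, and −0.02 and −0.055 for MII. Without B6 GV batch 2 replicate 1, a library with a low granulosa level, 650 genes differed between F1 and B6 in GV.

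**Figure D4:**
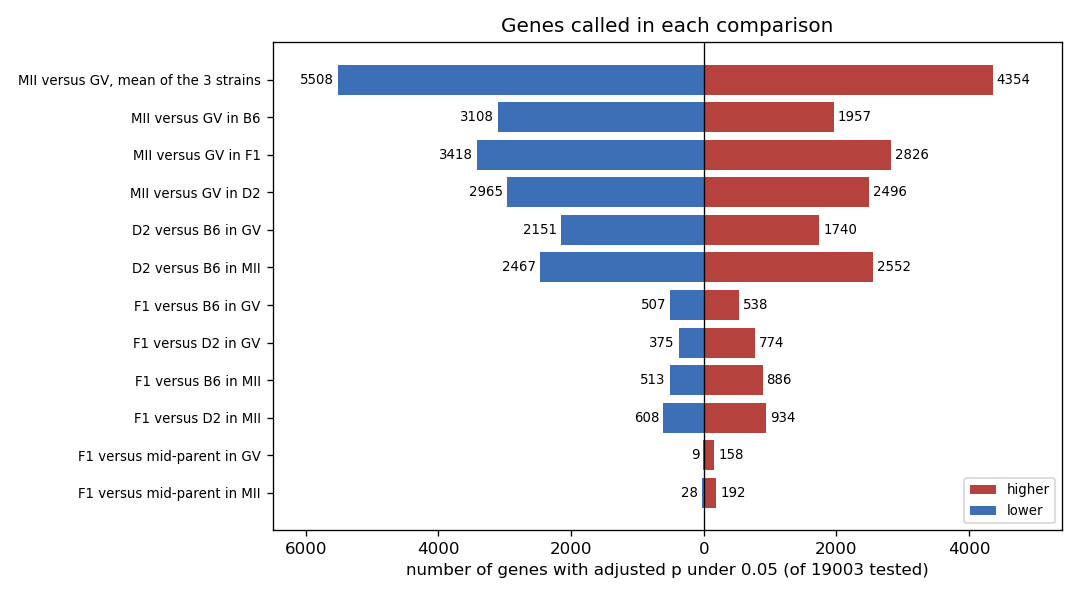
Number of genes with adjusted p under 0.05, of 19003 tested, that were higher (red, to the right) or lower (blue, to the left) in each of 12 comparisons. The 2 comparisons of F1 with the mid-parent gave 167 genes in GV and 220 in MII.

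Against the mid-parent, the mean of the parents' log2 levels, 167 genes differed in F1 GV oocytes (158 higher, 9 lower) and 220 in F1 MII oocytes (192 higher, 28 lower). The genes furthest above it were ones that differed strongly between the parents. Slc39a8, a zinc transporter, was higher by 3.75 ± 0.31 in GV and 3.68 ± 0.31 in MII on the log2 scale (SE). Bfsp1 was higher by 3.15 ± 0.21 and 3.10 ± 0.22, and Pnpla3, with F1 oocytes at 154 ± 33.6 CPM in GV (SD, n = 6), by 2.72 ± 0.13 in GV. Set against the arithmetic mean of the parents' levels, tested with limma-voom, only 2 genes were higher and 15 lower in GV. In MII 12 were higher and 55 lower. Slc39a8 was among those higher at both stages, at log2 differences of 1.33 ± 0.234 in GV and 1.165 ± 0.214 in MII (SE). On the log2 scale the same limma-voom fit called 207 genes higher in GV and 285 in MII. Among genes below the mid-parent in GV were Ccdc3, at −0.71 ± 0.15, and the phosphatase gene Ptpre, at −0.58 ± 0.11. In MII oocytes Cpeb1 was below it at −0.37 ± 0.09 (adjusted p = 0.0317, edgeR quasi-likelihood with Benjamini-Hochberg adjustment). Of the 78 ribosomal protein genes 5 were lower in F1 MII oocytes (11 adjusted over the list alone, median −0.25), with Rpl41 at −0.85 ± 0.15 and Rpl27 at −0.92 ± 0.18, and of the 78 respiratory chain genes 2 were lower, Cox4i1 at −1.27 ± 0.32 and Atp5o at −0.84 ± 0.22 (4 adjusted over the list alone). Neither list passed with an estimated correlation, at adjusted p = 0.613 and 0.43, and both did with the preset correlation, at 1.45e-11 and 4.71e-06. Against the mid-parent in MII, genes with transcripts of up to 1000 nt had a median log2 difference of −0.154, and those over 8000 nt 0.05. A shift by transcript length was not told apart from an effect of the hybrid on these lists. The granulosa list had a median of −0.95 in the same comparison, at adjusted p = 0.955 with an estimated correlation and 0.0259 with the preset correlation. Across all lists adjusted p with an estimated correlation ran from 0.349 to 0.995 in GV and from 0.43 to 0.994 in MII, and the signs of median, mean and test were mixed in 8 and 9 lists. At an unadjusted p under 0.05 there was 1 list at each stage, with the preset correlation 0 in GV and 3 in MII passed, and by fry 0 and 0.

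Batch 1 alone gave 70 genes against the mid-parent in GV, of which all 70 were higher, and batch 2 alone 79 (70 higher, 9 lower). In MII they gave 186 (139 higher, 47 lower) and 59 (58 higher, 1 lower), and none of the MII genes named as below the mid-parent passed in batch 2 alone. Rps27 and its retrotransposed copy Rps27rt, at −1.66 and −1.70 in MII, share reads.

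**Figure D5:**
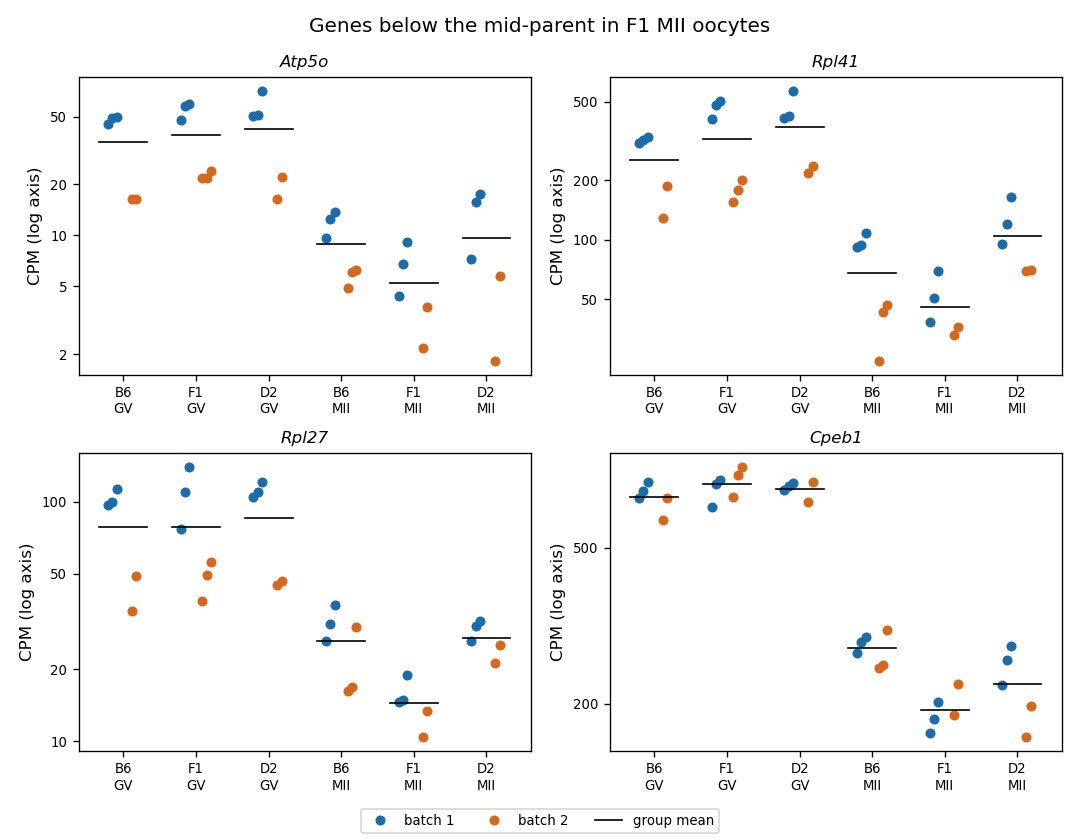
CPM (log axis) of Atp5o, Rpl41, Rpl27 and Cpeb1 in each library of the 6 groups, with batch 1 in blue, batch 2 in orange and black lines for group means. The F1 MII group mean was the lowest of the 3 MII groups for each gene, and batch 2 libraries lay lower than batch 1 libraries of the same group for Atp5o and Rpl41.

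Genes beyond both parents in the same direction were few. In GV oocytes this held for 1 gene, Rpap1, an RNA polymerase II associated protein, which was above B6 by 1.24 and above D2 by 1.17 on the log2 scale (adjusted p = 0.0221 and 0.0293, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and was named after its values were seen. Its F1 level was 32.6 ± 27.8 CPM (SD, n = 6). In MII oocytes it held for 32 genes, 5 above and 27 below, with Rpl27 at −0.93 against B6 and −0.915 against D2. Both tests use the same F1 libraries, so the overlap was set against simulations. Simulated libraries without a strain difference gave 0 such genes at either stage in 12 simulations. Simulated F1 libraries at the arithmetic mean of the parents gave a mean of 3.6 in GV (highest 6) and 2.2 in MII (highest 7). Counts were drawn independently for each gene and library, so a shift that many genes of a library share was not simulated. Independent lists of the observed sizes would share 21.9 genes above and 10 below in GV, and 43.5 and 16.4 in MII. When the F1 libraries were divided so that each parent met other F1 libraries, 0 genes remained in GV in either division, and 2 and 1 in MII, with Zfp933 in both. Batch 1 alone gave 29 genes in MII and 0 in GV, and batch 2 alone 0 in MII and 3 in GV. Limma-voom called 6 genes in GV and 49 in MII, and DESeq2 5 and 66. Without F1 MII batch 1 replicate 5 there were 12 genes in MII.

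Whether the change from GV to MII differed between strains was tested as an interaction. For D2 against B6, 20 genes passed, 9 with a higher and 11 with a lower change in D2, among them, by lowest adjusted p on each side, Pxdn at 3.29 ± 0.43 on the log2 scale (SE, adjusted p = 0.00021, edgeR quasi-likelihood with Benjamini-Hochberg adjustment) and Pknox2, a homeobox gene, at 3.07 ± 0.47, and Myo7a at −4.91 ± 0.78 and Elmo1 at −2.78 ± 0.45. At an unadjusted p under 0.05, 1820 genes passed. For F1 against the mid-parent 1 gene passed, with 1011 genes at an unadjusted p under 0.05. Batch 1 alone gave 20 and 2 genes and batch 2 alone 0 and 0 by edgeR, and DESeq2 gave 101 and 15 on all libraries. No list passed, at adjusted p from 0.793 to 0.888 for D2 and from 0.347 to 0.998 for F1 with an estimated correlation, with mixed signs in 2 and 5 lists. At an unadjusted p under 0.05 there were 0 and 2 lists, with the preset correlation 2 and 2 passed, and by fry 0 and 0.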

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

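The tests of granulosa-cell RNA were chosen after the stage differences and the marker levels had been seen, as were the granulosa covariate, the fits without 3 GV libraries, the arithmetic mid-parent and the make-up of the splits with more genes than the real one. The other tests here were set down before their results.

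Of 60 combinations of 10 library measures and 6 groups, 5 had a library far from the rest of its group, where chance gives about 1 in 20. The 10 highest genes held 9.94% of counts in B6 MII batch 1 replicate 1 (5.82% to 7.32% in the other 5) and 8.53% in F1 MII batch 1 replicate 4 (6.17% to 6.54% in the other 4). The stroma and blood marker level was −1.56 in B6 MII batch 2 replicate 2 (−1.21 to −1.01 in the other 5). The first principal component was 58.2 in B6 GV batch 2 replicate 1 (−108.9 to −66.6 in the other 4) and 23.2 in D2 GV batch 2 replicate 2 (−125.8 to −100.9 in the other 4), which are 2 of the 3 GV libraries with low granulosa marker levels. Of 219 named genes, the number with 1 library far from the rest was 17 in B6 GV, 10 in B6 MII, 14 in D2 GV, 11 in D2 MII, 14 in F1 GV and 16 in F1 MII. Table entries that named no gene held up to 0.019% of a library and were not analysed.

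The change from GV to MII differed between D2 and B6 at 20 genes. The difference in log2 change was 4.87 for Stc1, 3.29 for Pxdn, 3.07 for Pknox2, 2.65 for Mtx3, 1.30 for Alg11 and 0.85 for Nlrp2. It was −4.91 for Myo7a, −2.78 for Elmo1, −1.97 for Tex15, −1.74 for Iffo2, −1.67 for Cyb5r3 and −1.53 for Rps2. For F1 against the mid-parent it differed at 1 gene.

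The first pattern was the 3928 genes at least 2-fold lower in MII. The levels of Inhba and Hsd3b1, among the most abundant granulosa markers, were 319 and 329 CPM in GV, and removal of the zona would be a step that takes cumulus cells away. Among GV libraries alone, the slope on the granulosa marker level predicted 0.451 of the median log2 fold (−1.104 of −2.448 over 3910 genes), and 78.8% of the genes had a positive slope. RNA of granulosa cells in the GV pools may therefore account for part of it, and its share cannot be told apart from a loss of oocyte transcripts, since the marker level differs with stage. Scaling stays open too, since 2 other size factors moved the median of all genes by only −0.0407 and −0.0033. They kept at least 99.75% of the genes. Total RNA per oocyte was not measured, so loss of transcripts during maturation was not tested. For the 4354 genes higher in MII, the slope within GV libraries predicted 0.386 of the median log2 fold (0.163 of 0.423). Of these genes 19.9% had a positive slope, and 898 were still called higher with the granulosa level as a covariate. Granulosa-cell RNA in the GV pools may therefore account for part of the rises too.

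The second pattern was the lower ribosomal protein and respiratory chain transcripts in MII. The same slope predicted 0.064 of the median fold (−0.135 of −2.096), at 0.119 for the ribosomal list and −0.02 for the respiratory chain list. It was positive for 69 of 78 ribosomal genes (88.5%) and 35 of 78 respiratory chain genes (44.9%). These values argue against granulosa-cell RNA as the main cause, while a small part stays open for the ribosomal list. With the granulosa marker level as a covariate 70 of the 78 ribosomal genes were still lower. Transcript length, taken as that of the longest annotated transcript of a gene, was argued against as the sole cause. The 569 other genes matched on this length and level had a median of −0.07, or 0.033 of that of the lists. Their median length was 1317 nt against 1100 nt in the lists, and genes of up to 1000 nt had a median of −0.814. A part for length therefore stays open. Between batches the lists moved by −1.331 and the matched genes by −0.445, a ratio of 0.334, so a technical shift that acts on these lists beyond length stays open. A change in how well transcripts with short poly(A) tails are primed could give such a pattern too, and was not tested.

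The third pattern was the excess of F1 genes above the mid-parent. Of the genes above the mean of log2 levels by edgeR, 3.1% were also called above the arithmetic mean by limma-voom (2 of 158 in GV and 9 of 192 in MII). The test thus changed along with the scale. Limma-voom alone, however, called 207 genes above the mean of log2 levels in GV and 285 in MII. Against the arithmetic mean it called 2 and 12, which argues against the change of test as the main cause. The genes called by edgeR lay a median of 2.05 and 2.08 above the mean of log2 levels. From the arithmetic mean their medians were 0.078 and 0.104 (interquartile ranges −0.287 to 0.317 and −0.18 to 0.365). The log2 scale of the mid-parent is a candidate explanation for most of them, since a level at the arithmetic mean lies above the mean of logs when the parents differ strongly, and their median parental difference was 6.06 in GV and 5.81 in MII on the log2 scale.

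In 100 splits of the libraries for each of 16 counts of genes, the real one included, as many genes were called by 1 split, the real one, for 13 counts, by 2 for F1 against B6 in MII and for F1 against the mid-parent in MII, and by 3 for the D2 interaction. Splits were made within stage and batch for strain contrasts and within strain and batch for stage contrasts. For the stage counts and those of D2 against B6, 1 of 100 splits, the real one, reached the count. A chance labelling of the libraries is thus an unlikely source of them, which says nothing of other sources. These splits too mix stages or strains within a group, which widens the spread. For the F1 and interaction counts the splits cannot decide. They mix B6 and D2 libraries within a group, which widens the spread there, and 2 of these counts rest on a single gene. The stage mean had 9862 genes against 854 in the highest other split, with 5065 against 12 in B6, 6244 against 3942 in F1 and 5461 against 3162 in D2. D2 against B6 had 3891 against 0 in GV and 5019 against 3 in MII. F1 had 1045 against 2 (B6, GV), 1149 against 85 (D2, GV), 1399 against 1902 (B6, MII) and 1542 against 5 (D2, MII), and against the mid-parent 167 against 7 in GV and 220 against 472 in MII. Beyond both parents there were 1 against 0 in GV and 32 against 1 in MII, and for the F1 interaction 1 against 0. The 1 gene in GV was no more than an additive F1 gave in simulations (mean 3.6, highest 6), 0 remained with the F1 libraries divided, and the count ran from 0 to 7 with each library left out in turn. The D2 interaction had 20 against 903. The splits with more genes than the real one largely set B6 against D2 libraries. In that with 1902 and 472, 5 of the 6 MII libraries called B6 were B6 and 4 of the 5 called F1 were D2, and in that with 903, 4 of the 5 GV libraries called D2 were D2 and 4 of the 5 MII libraries called D2 were B6. A further split gave 749 genes for the D2 interaction, with 4 D2 libraries among the 5 GV libraries called B6 and 4 B6 libraries among the 6 MII libraries called B6. Its MII labels lay over the 2 sets of batch 2 as the real ones do. Such counts point to a structure of the samples, in which strain has a part and a part of the sets is not excluded. With a term for the sets the real count was 23.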

How the results depend on the processing

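The granulosa covariate, the fits without 3 GV libraries of low granulosa level and the arithmetic mid-parent were chosen after seeing the data. Of 305 values of named genes, 304 kept direction and side of the threshold with DESeq2, 302 with median-of-ratios scaling, 303 with upper-quartile scaling, 292 with limma-voom, 252 in batch 1 alone, 220 of 304 in batch 2 alone and 283 with the granulosa covariate. Reversed values were Glo1 in MII in batch 1 alone (−0.27), Hbb-bs between stages with the granulosa covariate (2.58), and the subcortical maternal complex list by fry (adjusted p = 0.00346). The granulosa covariate is confounded with stage. Fits on 1 batch or on the compared groups use fewer libraries. Elsewhere the cause was not tested. Depth limits genes with few reads, as at 3 counts per stage.

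At a threshold of at least 2-fold, counts were 4083 for the stage mean, 2694 in B6, 2993 in F1 and 2728 in D2, 2003 and 2798 for D2 against B6 in GV and MII, 444, 566, 669 and 834 for F1 against B6 and D2 in GV and then MII, and 18 beyond both parents in MII, with median positions of −0.033 in GV and −0.053 in MII.

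In batch 1 alone, counts were 3590 for the stage in D2, 2449 for D2 against B6 in GV, 216, 474, 640 and 907 for F1 against its parents in the same order, 70 against the mid-parent in GV, 2 for the F1 interaction and 0 beyond both parents in GV, with a GV position of −0.062. In batch 2 alone they were 4503 for the stage mean, 1384 in B6, 812 in F1, 769 in D2, 1942 and 2160 for D2 against B6, 325 for F1 against D2 in GV, 223 and 343 for F1 against B6 and D2 in MII, 79 and 59 against the mid-parent, 0 and 0 for the D2 and F1 interactions, and 3 and 0 beyond both parents, with positions of 0.111 and −0.055 and 4 stage lists.

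With the granulosa covariate, counts were 2497 for the stage mean, 1612 in B6, 1619 in F1, 1542 in D2, 48 and 2 for the interactions and 6 beyond both parents in GV. Without the 3 GV libraries they were 560 for F1 against B6 in GV, 42 and 3 for the interactions and 0 beyond both parents in GV, with a GV position of −0.041. Without a batch term they were 3566 and 3010 for the stage in F1 and D2, 2558 for D2 against B6 in GV, 416, 618, 684 and 842 for F1 against its parents, 128 against the mid-parent in MII, 13 and 0 for the interactions and 5 beyond both parents in MII. With the compared groups alone they were 3353 for the stage in D2, and 0 and 14 beyond both parents.

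Numbers repeated between groups did not pair the libraries. The median correlation of residuals was −0.034 over 59 pairs with the same number and −0.045 over 157 with different numbers. With a replicate block, counts were 916 for F1 against B6 in MII, 7 and 0 for the interactions and 13 beyond both parents in MII. With a replicate block by strain, batch and number they were 1430, 3955 and 3368 for the stage in B6, F1 and D2.

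Limma-voom gave 1829 for F1 against B6 in GV, 2285 and 2405 for F1 against B6 and D2 in MII, 352 against the mid-parent in MII, 4 for the F1 interaction, and 6 and 49 beyond both parents, with a GV position of −0.055. DESeq2 gave 387 against the mid-parent in MII, 101 and 15 for the interactions, and 5 and 66 beyond both parents. Beyond both parents in GV there were 4 genes with median-of-ratios scaling, 2 with upper quartile, 3 with no filter, 4 with the stricter filter and 0 with a batch term of 3 levels. Against the arithmetic mid-parent 17 and 67 genes passed. By camera with the preset correlation 14 stage lists passed, 3 lists for the F1 mid-parent in MII and 2 for each interaction, and by fry 19 for the stage, 2 for D2 against B6 in GV and 6 in MII.

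With each library left out in turn, counts ran from 9360 to 10300 for the stage mean, 3874 to 5496 in B6, 5092 to 6556 in F1 and 3761 to 5780 in D2. They ran from 3348 to 3976 and 4546 to 5207 for D2 against B6, 650 to 1171 and 965 to 1237 for F1 against B6 and D2 in GV, and 1031 to 1519 and 1241 to 1630 in MII. Against the mid-parent they ran from 140 to 180 and 168 to 226, for the interactions from 11 to 41 and 1 to 3, and beyond both parents from 0 to 7 and 12 to 36, with positions from −0.026 to 0.038 and −0.036 to −0.009. F1 against B6 in GV fell to 650 without B6 GV batch 2 replicate 1. The D2 interaction had 11 genes without B6 GV batch 2 replicate 2, 13 without D2 GV batch 2 replicate 1 and 41 without D2 GV batch 2 replicate 2. The F1 interaction had 3 without B6 GV batch 2 replicate 1 and 2 without B6 MII batch 2 replicate 3. Beyond both parents in MII there were 12 without F1 MII batch 1 replicate 5, 18 without D2 MII batch 1 replicate 3, 19 without D2 MII batch 2 replicate 1 and 21 without F1 MII batch 2 replicate 2. Beyond both parents in GV, where 1 gene passed, there were 0 without B6 GV batch 2 replicates 1 or 2 or D2 GV batch 2 replicate 2. There were 2 without F1 GV batch 2 replicates 2 or 3, F1 MII batch 1 replicate 5, D2 MII batch 1 replicate 2 or D2 GV batch 1 replicate 5, and 3 without D2 MII batch 2 replicate 2, F1 GV batch 1 replicate 5 or D2 GV batch 1 replicate 4. There were 4 without F1 GV batch 1 replicates 2 or 3, 5 without B6 GV batch 1 replicate 4 or F1 MII batch 1 replicate 4, 6 without D2 GV batch 2 replicate 1 and 7 without B6 MII batch 1 replicates 2 or 3. The median position without B6 GV batch 1 replicate 5 was 0.038 in GV, and without D2 MII batch 1 replicate 4 it was −0.036 in MII.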

Other observations

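The comparisons with the arithmetic mean of the parents were chosen after the data had been seen, and the genes named in the first paragraph were chosen after their values were seen.

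Cdc5l, a splicing factor gene, was at 6.16 ± 4.74 CPM in B6 GV (SD, n = 5), 136 ± 15.1 in D2 GV (n = 5) and 12.2 ± 2.95 in F1 GV (n = 6), and at 1.47 ± 0.626 (n = 6), 168 ± 8.4 (n = 5) and 9.9 ± 5.34 (n = 5) in MII. In GV it lay below the arithmetic mean of the parents at −2.56 ± 0.19 on the log2 scale (SE). Against the mean of log2 levels it did not pass in edgeR's test, at −1.25 in GV (adjusted p = 0.0721) and −0.68 in MII (adjusted p = 0.499), and in MII the F1 was above B6 by 2.75 (adjusted p = 3.27e-05). Slc39a8 was at 0.273 CPM in B6 GV, 34.5 in D2 GV and 41.7 in F1 GV. Zfp933, a zinc finger gene, was at 11.7 CPM in B6 MII, 11.3 in D2 MII and 24.6 ± 5.48 in F1 MII (SD, n = 5). Reads of these genes were aligned to a B6-derived genome, and copies at other sites of the D2 genome were not examined.

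Genes that differed between D2 and B6 in the same direction were next to each other on the chromosomes more often than permuted positions gave. In GV there were 561 such pairs of neighbours among 15175 protein-coding genes, against a mean of 356 and a highest of 423 in 10000 permutations, and in MII 813 against 593.1 and 683 (permutation p = 1e-04 for each, the smallest they can give). For the stage difference there were 2727 against 2358.3 and 2526.

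The batches differed by transcript length, taken as that of the longest annotated transcript of a gene. Genes with transcripts of up to 1000 nt had a median log2 difference of −0.981 between batch 2 and batch 1 and of −0.814 between MII and GV (742 genes), and those over 8000 nt had 0.333 and 0.182 (881 genes). The abundant transcript AY036118 held 1.21% to 3.8% of counts in batch 1 libraries and 0.11% to 0.69% in batch 2 libraries.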
